A study of Mus musculus with 16 samples.

How the data were processed

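Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to GRCm38 with STAR 2.7.3a, counted per gene with HTSeq and normalized with DESeq2. RNA was purified with an RNeasy micro kit and made into poly(A)-selected libraries with an in-house protocol. The annotation release, the strand of the libraries and any filter on genes are not given in the sources used here, so genes that overlap or have close copies are uncertain.

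The deposited signal values are DESeq2-normalized counts by the authors, 1 table for P1 and 1 for P14, rounded to 2 decimals. Every positive value (100% in each library) was a whole multiple of the library's value for 1 read within a tolerance of 0.0051, so whole reads were recovered by division. The tables hold 19748 genes at P1 and 19014 at P14, of which 19713 and 18980 matched the GRCm38 reference by Ensembl ID, and 18268 genes are in both. The tables were normalized separately, so values were not compared between ages except through recovered reads.

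Within each age PNS was compared with Ctrl by limma 3.58.1 (limma-trend, R 4.3.3) on log2(value + 1), for genes with a mean of at least 10, with Benjamini-Hochberg adjustment at 0.05. The difference between ages was the PNS effect at P14 minus that at P1 in 1 limma fit of all 16 libraries. Development in controls was tested with edgeR 4.0.16 (quasi-likelihood, TMM) on recovered reads of genes in both tables, in a model of all 16 libraries. The unit turned out to be normalized values from which reads can be recovered, so the route set out for normalized values was kept for PNS against Ctrl and recovered reads were used for age. The count models for PNS against Ctrl (edgeR, DESeq2 1.42.0 and voom on recovered reads) were added later as alternatives.

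The 34 gene lists with 852 genes, the comparisons, the thresholds and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with fry, and with an exact two-sided permutation test of list scores, each adjusted over the lists. Fits that added a covariate for each library used camera at the preset correlation only. The lists cover interneurons (pan-GABAergic, medial and caudal ganglionic eminence, GABA receptors and chloride transporters), projection neurons, progenitors, immature neurons, synapses, glia, vessels, blood, meninges, choroid plexus, neighbouring tissues, hormone and stress responses, perineuronal nets and general metabolism.

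Genes were named by these rules. Where genes passed, the 10 with the largest change in each direction, a mean of at least 50 and no overlap between groups were named. Where fewer than 5 passed, the 5 with the smallest p in each direction were named as well. Up to 4 genes with the smallest p were named from each list that passed. For the difference between ages 5 genes in each direction were named. Gad1, Gad2, Slc32a1, Lhx6, Sst, Pvalb, Vip, Htr3a, Reln, Npy, Cck, Calb2, Nr3c1, Nr3c2, Fkbp5, Slc12a2, Slc12a5 and Mbp were named whatever their values, and for development in controls only these were. Predicted genes were counted and named only where they ranked among the first 5. Some genes that these rules name are not reported here.

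A self-test with simulated counts of the same size and spread gave, of 100 changed genes at each size, 59 calls at 1.5-fold and 90 at 2-fold for P1, 71 and 99 for P14, 30 and 78 for the difference between ages, and 66 and 95 for development. The changed genes were drawn from those with a mean of at least 50, so these rates do not cover the weaker genes that were also tested. False calls were 13 of 162, 15 of 185, 4 of 112 and 8 of 169. A simulated 1.25-fold change of the medial eminence list was called at both ages, with 1 other, unchanged list called at P1 and 0 at P14. The simulated genes varied independently of each other, whereas correlations estimated within the real lists at P1 reached 0.97. The simulated list calls therefore do not show how often lists are called falsely in these data.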

Results

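Poly(A) RNA of the medial prefrontal cortex was sequenced from male ICR mice born to dams that had been stressed during pregnancy (prenatal stress, PNS) or left unstressed (Ctrl). Tissue came from pups of 1 day (P1) or 14 days (P14), with 4 libraries in each of the 4 groups, 16 in all. The reads recovered per library ranged from 34.0 M to 58.8 M at P1 and from 15.1 M to 73.0 M at P14. The P1 groups averaged 42.0 ± 8.3 (Ctrl) and 52.7 ± 4.5 (PNS) M reads, and the P14 groups 48.8 ± 25.4 and 31.8 ± 6.3 M (SD, n = 4 each). Levels are normalized read counts given as mean ± SD over the 4 libraries of a group, and fold changes are on the log2(value + 1) scale, which understates changes of weakly expressed genes. The labels do not say that the libraries come from separate litters or animals, so the p-values measure the spread between these samples, whatever its source. All replicate pairs differed by more than sampling noise (chi-square per gene from 6.54 to 65.3).

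The first comparison asked what stress before birth had changed in the cortex at P1. Genes of meninges, blood vessels and the neighbouring olfactory bulb stood higher in PNS and genes of deep-layer cortical projection neurons stood lower, with medians of 0.56 for meningeal fibroblasts and -0.16 for deep layers on the log2 scale. None of these list calls held with an estimated correlation, where the smallest adjusted p was 0.337. Among single genes Sema3c, a secreted axon guidance semaphorin, had the smallest p: it averaged 3264 ± 185 in Ctrl and 2255 ± 161 in PNS. The interneuron lists did not pass. At the preset correlation the pan-GABAergic list was called lower with the olfactory bulb score as a covariate (median -0.15). With depth as a covariate it was called higher (median 0.25). Reln, the extracellular glycoprotein of Cajal-Retzius cells and of a class of interneurons, averaged 18894 ± 2720 in Ctrl and 26056 ± 3840 in PNS. Reln was highest in PNS replicates 2 and 3, which also had the highest olfactory bulb scores (1.66 and 1.40), and in PNS replicate 4 it lay below Ctrl replicate 4.

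No gene passed the limma test at P1: 0 of 16711 genes had an adjusted p below 0.05. An unadjusted p below 0.05 was found in 1115 (765 higher and 350 lower in PNS, 836 expected by chance). edgeR called 0 of 16832 genes, with 1195 at unadjusted p below 0.05, while DESeq2 called 57 higher and 13 lower. The 2 groups did not overlap in 540 genes, or 3.23%, against the 2.86% that chance gives. Without PNS replicate 4 the limma count was 123 (120 higher and 3 lower), and in 103 of those 120 genes the omitted library lay at or below the highest control. Without Ctrl replicate 1 it was 1, the predicted gene Gm7887, named after its values were seen (log2 difference -2.70, adjusted p = 0.0351).

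The genes with the smallest p in each direction did not pass limma and did pass DESeq2. Sema3c (ENSMUSG00000028780, GRCm38 chromosome 5, 17574281 to 17730268) was lower by 30.9% in PNS, with a log2 difference of -0.53 ± 0.0679 (SE), a limma adjusted p of 0.198 and a DESeq2 adjusted p of 1.07e-07. All 4 PNS libraries lay below all 4 controls for Sema3c, and its limma adjusted p was 0.0195 with all 16 libraries in 1 fit and 0.0212 without PNS replicate 4. Pantr1, a long noncoding RNA (ENSMUSG00000060424, chromosome 1, 42590782 to 42694842), averaged 2440 ± 191 in Ctrl and 1866 ± 80.2 in PNS. Ephb1, a receptor for ephrin-B ligands, averaged 5000 ± 331 and 3949 ± 187. Hs6st2, which sulfates heparan sulfate, had a log2 difference of -0.46, and Exosc9, a subunit of the RNA exosome, one of -0.42. In the other direction Plat, the tissue plasminogen activator (ENSMUSG00000031538, chromosome 8, 22757727 to 22782844), averaged 1817 ± 101 in Ctrl and 2285 ± 124 in PNS. Serpinf1, a secreted serpin also called pigment epithelium-derived factor, averaged 1255 ± 146 and 2022 ± 410, Stom (stomatin) 673 ± 92.8 and 945 ± 60.7, Aifm3 183 ± 22.9 and 327 ± 71.8, and Cox6b2, a cytochrome c oxidase subunit, 58.5 ± 4.82 and 112 ± 23.3. For these 9 genes beside Sema3c the limma adjusted p was 0.669, and the DESeq2 adjusted p ranged from 0.0025 (Pantr1) to 0.017 (Cox6b2). Without PNS replicate 4 the limma adjusted p was 0.0452 for Plat, 0.0276 for Cox6b2 and 0.022 for Serpinf1.

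Of the 34 gene lists fixed before the data were examined, 16 were called at P1 by camera with a preset correlation of 0.01, and 0 with an estimated correlation. The smallest adjusted p with an estimated correlation was 0.337. The fry test, which asks whether a list's genes move on balance in 1 direction, called 0. An exact permutation test of the list scores called 0. Its smallest possible p was 0.0286, so after adjustment over the 34 lists no list could pass on its own, and this 0 says little. Meningeal fibroblast genes stood higher in PNS, all 22 of 22 of them (adjusted p = 1.01e-19, and adjusted p = 0.365 with an estimated correlation). For this list 0 genes were called over all genes and 15 were called when adjusted over the list alone. Aldh1a2, which makes retinoic acid, averaged 1207 ± 127 in Ctrl and 1870 ± 460 in PNS, Slc6a13, a GABA and taurine transporter of the leptomeninges, 1913 ± 210 and 3276 ± 994, and Col3a1, a fibrillar collagen, 8559 ± 259 and 12535 ± 2963. Without PNS replicates 2 and 3 the median of the list was 0.25, and without PNS replicates 1, 2 and 3 it was 0.13. The meningeal scores were 0.53 and 0.69 in PNS replicates 2 and 3 and -0.07 in replicate 4, and with the olfactory bulb score of each library as a covariate the median was 0.27. Endothelial genes were positive in 20 of 22 (median 0.19, adjusted p = 4.1e-09, and adjusted p = 0.365 with an estimated correlation), among them Itm2a (0.39), Ramp2 (0.29), Esam (0.21) and Nos3 (0.32), with 0 called over all genes and 1 adjusted over the list alone. Pericyte and smooth muscle genes were positive in 13 of 15 (median 0.30, adjusted p = 9.12e-06, and adjusted p = 0.365 with an estimated correlation), with Vtn at 0.61, Anpep at 0.55, Acta2 at 0.54 and Myh11 at 0.50. Without PNS replicate 3 the pericyte median was 0.18, and without Ctrl replicate 3 the endothelial median was 0.12. With the olfactory bulb score as a covariate the medians were 0.21 for pericyte and 0.12 for endothelial genes.

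Olfactory bulb genes, included because the bulb borders the dissected cortex, were positive in 13 of 15 members (median 0.55, adjusted p = 5.72e-06, and adjusted p = 0.415 with an estimated correlation). The shift was carried by 3 of the 4 PNS libraries: the list scores, which are mean log2 deviations from each gene's mean, were 0.90, 1.66 and 1.40 in PNS replicates 1 to 3 and -1.19 in replicate 4, against 0.14, -1.12, -0.67 and -1.13 in the controls. Cdhr1, a protocadherin of mitral cells, was counted at 4006, 8889 and 6097 in PNS replicates 1 to 3 and at 175 in replicate 4, with 264 to 1158 in the controls. Doc2g averaged 25.4 ± 17.7 and 88.7 ± 48.1, Slc6a3, the dopamine transporter, 10.5 ± 3.37 and 28.4 ± 10.5, Omp, the olfactory marker protein, 9.60 ± 4.19 and 92.6 ± 65.6, and Tbx21, a mitral cell transcription factor, 36.1 ± 35.7 and 350.2 ± 267. Over all genes 0 members were called, and 2 (Doc2g and Slc6a3) were when adjusted over the list alone. Without PNS replicate 4 the median was 1.08, without Ctrl replicate 3 it was 0.83, without Ctrl replicate 4 it was 0.35, without PNS replicates 2 and 3 it was 0.11 with a camera adjusted p of 0.102, and without PNS replicates 1, 2 and 3 it was -0.08. With log2 recovered reads as a covariate it was 1.13. The first principal component of the P1 libraries (35.8% of the variance) placed PNS replicates 1, 2 and 3 at 10.7, 36.6 and 37.5, PNS replicate 4 at -24.9 and the controls from -28.3 to -1.53.

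**Figure D1:**
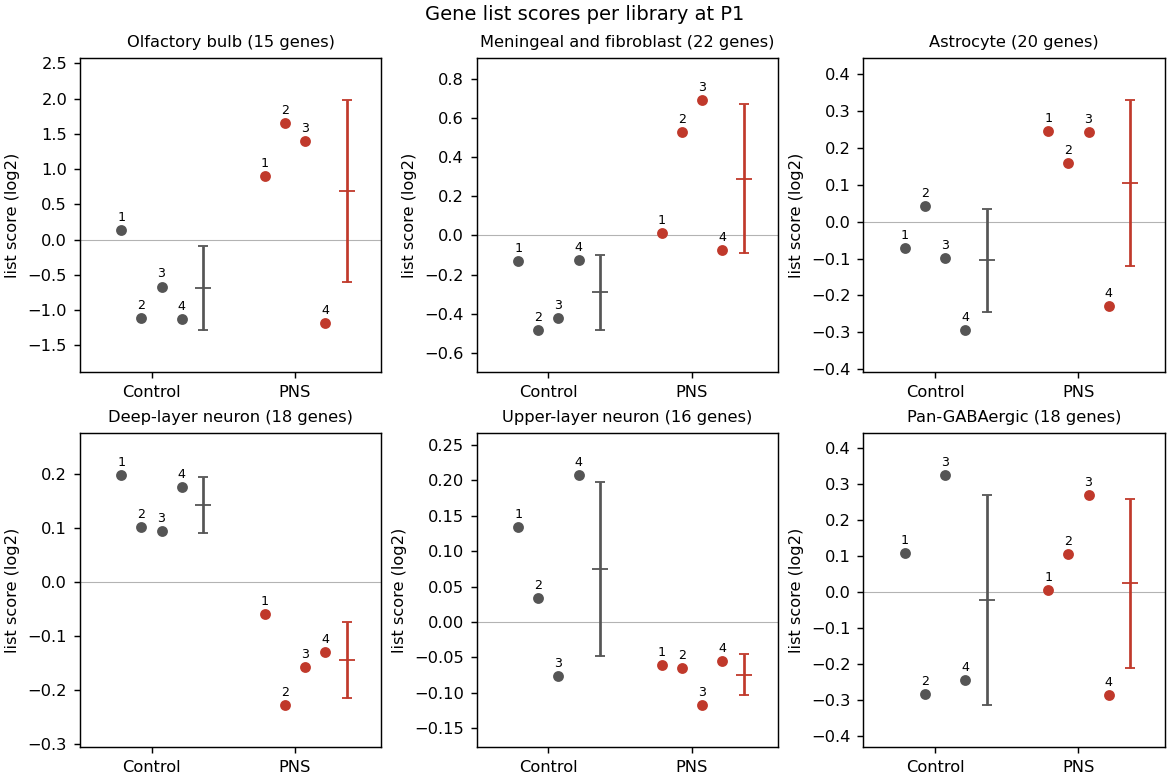
Scores of gene lists at P1, as the mean over a list's genes of log2(value + 1) minus each gene's mean over the 8 libraries (vertical axis, log2 units), for Ctrl and PNS; points are libraries labelled by replicate number and bars are mean ± SD (n = 4). All 4 PNS libraries lie below all 4 controls for deep-layer genes (-0.23 to -0.06 against 0.09 to 0.20), while in the olfactory bulb list PNS replicate 4 (-1.19) lies below every control (-1.13 to 0.14).

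Deep-layer projection neuron genes, which mark the cortical output layers, were negative in 17 of 18 members (median -0.16, adjusted p = 3.65e-05, and adjusted p = 0.337 with an estimated correlation). The 4 PNS scores (-0.06, -0.23, -0.16 and -0.13) all lay below the 4 control scores (0.20, 0.10, 0.09 and 0.18), with an exact permutation p of 0.0286, which is the smallest possible, and an adjusted p of 0.324 over the 34 lists. Syt6 averaged 4458 ± 875 in Ctrl and 3382 ± 421 in PNS, Sox5, a transcription factor of corticofugal neurons, 3234 ± 468 and 2608 ± 203, Tle4 6643 ± 1023 and 5309 ± 694, and Cplx3 27.2 ± 9.99 and 9.47 ± 7.59. Although 7 members had an unadjusted p below 0.05, 0 were called over all genes and 0 when adjusted over the list alone. Upper-layer genes were negative in 12 of 16 (median -0.13, adjusted p = 0.00828, and adjusted p = 0.365 with an estimated correlation), with Lhx2 at -0.30, Pou3f3 at -0.28 and Pou3f2 at -0.38. Immature neuron genes were negative in 18 of 20 (median -0.10, adjusted p = 0.0113, and adjusted p = 0.55 with an estimated correlation). Among them Igfbpl1 stood at -0.36, Neurod2 at -0.17 and Draxin at -0.12, while Nhlh2 stood at 0.21. Without Ctrl replicate 4 the adjusted p was 0.0608 for upper-layer genes (median -0.04) and 0.157 for immature neuron genes (median -0.06), and the immature neuron call also ended without PNS replicate 1. The deep-layer median was -0.26 without PNS replicate 4, and the upper-layer median -0.20 without Ctrl replicate 3. With the olfactory bulb score as a covariate the immature neuron call ended (median -0.01), and the medians were -0.21 for deep-layer and -0.19 for upper-layer genes. In PNS replicates 1 to 3 the olfactory bulb genes above stood highest.

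Striatal projection neuron genes, a second neighbouring tissue, were negative in 18 of 20 (median -0.22, adjusted p = 0.0046, and adjusted p = 0.55 with an estimated correlation), with Pde10a at -0.20, Rgs9 at -0.25, Ppp1r1b at -0.43 and Foxp1 at -0.31. Ctrl replicate 1 had the highest striatal score (0.95), and without it the median was 0.04 with an adjusted p of 0.684, while without PNS replicate 4 the adjusted p was 0.0735 (median -0.13). Thalamic genes were positive in 10 of 13 (median 0.18, adjusted p = 0.00383, and adjusted p = 0.443 with an estimated correlation), with Lef1 at 0.40, Tnnt1 at 0.99 and Plekhg1 at 0.18. Lhx2, which the list shares with the upper layers, stood at -0.30. The thalamic median was 0.28 without PNS replicate 4, 0.27 without Ctrl replicate 1, and 0.09 without PNS replicates 2 and 3 (adjusted p = 0.202). With the olfactory bulb score as a covariate the thalamic call ended (median 0.07), and the striatal median was -0.43. Choroid plexus genes (median 0.38) missed the threshold with an adjusted p of 0.0625.

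Astrocyte genes were positive in 13 of 20 (median 0.14, adjusted p = 0.00176, and adjusted p = 0.559 with an estimated correlation). In it 0 genes were called over all genes and 4 adjusted over the list alone: Id3 (2314 ± 259 and 2950 ± 49.4), Gjb6 (423 ± 111 and 919 ± 325), Gja1 (3727 ± 534 and 6130 ± 1976) and S100b (42.9 ± 10.7 and 107 ± 49.4). Without PNS replicate 1 the astrocyte adjusted p was 0.0741 (median 0.06), without Ctrl replicate 4 it was 0.123 (median 0.03), and the median was 0.08 without PNS replicate 3, 0.09 without Ctrl replicate 1 and 0.21 without PNS replicate 4. S100b was counted at 133, 157 and 93.8 in PNS replicates 1 to 3, which had high olfactory bulb scores, and at 44.4 in replicate 4. With the olfactory bulb score as a covariate the astrocyte median was -0.02, with the test in the negative direction, and with log2 recovered reads as a covariate it was 0.06. Glucocorticoid-responsive genes were positive in 17 of 22 (median 0.10, adjusted p = 0.000385, and adjusted p = 0.365 with an estimated correlation), with 0 called over all genes and 3 adjusted over the list alone (Gjb6, Map3k6 at 0.65 and Tgm2 at 0.35). Hif3a stood at 0.45, and Tsc22d3, a direct target of the glucocorticoid receptor, at -0.10. Without PNS replicate 3 the glucocorticoid-responsive median was 0.07, and with the olfactory bulb score as a covariate it was 0.06 (camera adjusted p = 0.0387). Myelin genes were positive in 14 of 21 (median 0.13, adjusted p = 0.0138, and adjusted p = 0.55 with an estimated correlation). Enpp2 stood at 0.59, Aspa at 1.36 and Mal at 0.86, whereas Mbp, the myelin basic protein, stood at -0.16. The myelin call ended without Ctrl replicate 4 (adjusted p = 0.0879), PNS replicate 1 (0.0648) or PNS replicate 3 (0.0771, median 0.07), and the median was 0.22 without Ctrl replicate 3. It ended as well with the olfactory bulb score as a covariate (median -0.02, with the test in the positive direction).

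Interferon-stimulated genes were positive in 20 of 24 (median 0.23, adjusted p = 0.00256, and adjusted p = 0.559 with an estimated correlation), with Ifi27 at 0.71, Psmb9 at 0.52, Isg15 at 0.54 and Ifitm3 at 0.34. The interferon adjusted p was 0.0846 without PNS replicate 2 (median 0.11), and the median was 0.51 without PNS replicate 4. With the olfactory bulb score as a covariate the interferon list was lower in PNS (median -0.05). Mitochondrially encoded genes were positive in 7 of 7 (median 0.18, adjusted p = 0.0217, and adjusted p = 0.621 with an estimated correlation). mt-Nd6 stood at 0.33, mt-Nd5 at 0.21, mt-Nd4 at 0.19 and mt-Nd1 at 0.15. The mitochondrial call ended without Ctrl replicate 1 (adjusted p = 0.152), Ctrl replicate 2 (0.0643), Ctrl replicate 3 (0.227), PNS replicate 3 (0.221) or PNS replicate 4 (0.108). The mitochondrial median was 0.34 without Ctrl replicate 4 and 0.28 without PNS replicate 2. Ribosomal protein genes were negative in 69 of 80 (median -0.06, adjusted p = 2.48e-05, and adjusted p = 0.55 with an estimated correlation), with Rpl23a at -0.14, Rps16 at -0.11, Rps4x at -0.12 and Rpl18 at -0.10. Protein folding genes were negative in 21 of 27 (median -0.08, adjusted p = 0.0266, and adjusted p = 0.559 with an estimated correlation), with Hsp90b1 at -0.16, Hsph1 at -0.19, Hspd1 at -0.12 and Manf at -0.15. The folding call ended without Ctrl replicate 2 (adjusted p = 0.384), PNS replicate 2 (0.095) or PNS replicate 4 (0.108), and the median was -0.05 without PNS replicate 3. With the olfactory bulb score as a covariate the ribosomal protein (median -0.03) and folding (-0.04) calls ended. With log2 recovered reads as a covariate these medians were -0.11 and -0.14.

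Inhibitory neurons are the cell class that the study is about. Pan-GABAergic genes (adjusted p = 0.639), genes of interneurons from the medial ganglionic eminence (0.655), genes of interneurons from the caudal ganglionic eminence (0.0712) and GABA receptor and chloride transporter genes (0.6) did not pass at P1. Pan-GABAergic genes were lower in PNS with the olfactory bulb score as a covariate (median -0.15, against 0.02 without it, camera adjusted p = 0.00855). With log2 recovered reads as a covariate they were higher (median 0.25, camera adjusted p = 0.00566). Both calls used the preset correlation and were not repeated with an estimated one, which was 0.24 for this list without a covariate. Gad1, which makes GABA, averaged 4118 ± 2039 in Ctrl and 4852 ± 1667 in PNS, Gad2 1666 ± 657 and 1752 ± 597, and Slc32a1, the vesicular GABA transporter, 2470 ± 967 and 2804 ± 984. Lhx6, the transcription factor of medial ganglionic eminence interneurons, averaged 5558 ± 330 and 5000.2 ± 499, Sst 4694 ± 754 and 5326 ± 712, and Npy 2096 ± 475 and 3071 ± 928. Vip averaged 106 ± 43.8 and 133 ± 26.8, Calb2 1359 ± 358 and 2366 ± 1145, Cck 3116 ± 151 and 2824 ± 162, and Htr3a 163 ± 58.8 and 195 ± 27.5. Reln (ENSMUSG00000042453, chromosome 5, 21884454 to 22344702) had a log2 difference of 0.46 ± 0.122 (SE) and a limma adjusted p of 0.669. In the caudal eminence list 0 genes were called over all genes and 3 adjusted over the list alone, Reln, Nr2f2 (0.57) and Ndnf (0.33), the last pair named after their values were seen. The corticosteroid receptors Nr3c1 (959 ± 77.5 and 1103 ± 207) and Nr3c2 (883 ± 242 and 1012 ± 191), and their co-chaperone Fkbp5 (3307 ± 250 and 3209 ± 250) did not pass. Neither did the chloride transporters Slc12a2 (1673 ± 144 and 1704 ± 226) and Slc12a5 (6943 ± 1319 and 7349 ± 1557), and over these 5 genes the limma adjusted p ran from 0.811 to 0.976. Leaving out 1 library flipped the sign for Gad2 (-0.11 without Ctrl replicate 4), Slc32a1 (-0.02 without PNS replicate 3), Slc12a2 (-0.04 without PNS replicate 3), Slc12a5 (-0.05 without PNS replicate 3) and Fkbp5 (0.0045 without Ctrl replicate 4).

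**Figure D2:**
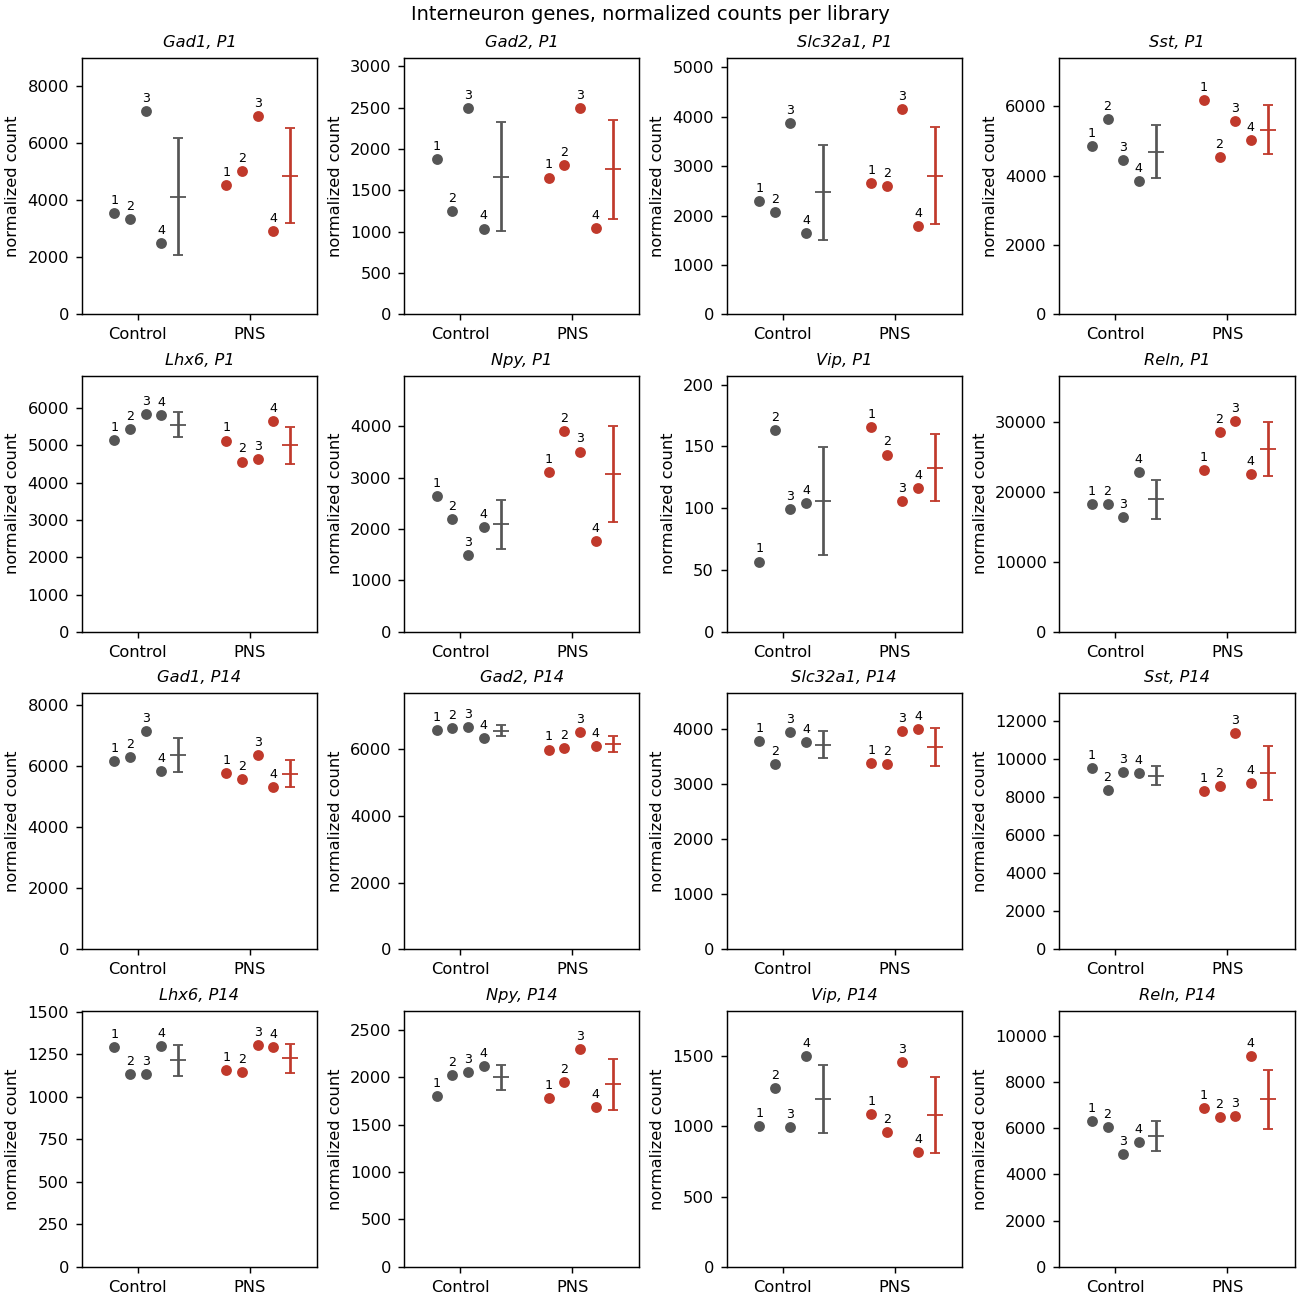
Normalized read counts (vertical axes, each starting at 0) of interneuron genes in Ctrl and PNS at P1 and P14; points are libraries labelled by replicate number and bars are mean ± SD (n = 4). None of the genes passed the limma test at either age, and Reln averaged 18894 and 26056 at P1 and 5660 and 7245 at P14.

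The other lists did not pass at P1. Their adjusted p-values were 0.0625 for nuclear-encoded oxidative phosphorylation genes, 0.365 for receptors and enzymes of the stress axis, and 0.365 for microglia. They were 0.386 for oligodendrocyte precursors, 0.403 for glutamatergic synapse genes, 0.667 for immediate early genes, 0.92 for perineuronal net genes and 0.973 for neural progenitor and for proliferation genes. Monoamine receptor, erythroid and cholesterol synthesis genes had an adjusted p of 0.655 and hypoxia and glycolysis genes one of 0.756. In the hypoxia list the median (0.02) was positive while the mean (-0.01) and the test were negative. Neural progenitor genes had a median of -0.04, a mean of -0.00142 and a test in the positive direction. A further 8 lists were called at P1 with the olfactory bulb score as a covariate, pan-GABAergic genes among them. These calls used camera at the preset correlation of 0.01 and were not repeated with an estimated one. Without the covariate the estimated correlation was 0.87 for proliferation, 0.67 for microglia and 0.48 for neural progenitor genes, so the p-values may be far too small. The score averaged -0.69 in Ctrl and 0.69 in PNS, so it is hard to tell apart from stress. Lower in PNS were proliferation (median -0.37, adjusted p = 2.24e-30), neural progenitor (-0.33, 6.56e-11), microglia (-0.24, 0.000929), oligodendrocyte precursor (-0.14, 0.000788) and immediate early genes (-0.11, 0.000929). Oxidative phosphorylation (0.03, 0.00116) and cholesterol synthesis genes (0.07, 0.00272) were higher. With log2 recovered reads as a covariate cholesterol synthesis genes were lower (median -0.08, adjusted p = 0.00554) and choroid plexus genes higher (0.57, 0.000478).

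The second comparison asked the same of the cortex at P14. Activity-regulated immediate early genes stood higher in PNS, with Nr4a3, an activity-induced nuclear receptor, at 2047 ± 182 in Ctrl and 3190 ± 289 in PNS. The median of the list was 0.36, and 0.16 with log2 recovered reads as a covariate. Ribosomal protein genes and nuclear-encoded genes of oxidative phosphorylation stood slightly higher, by medians of 0.12 and 0.08 on the log2 scale. Proliferation genes stood lower (median -0.15), and so did pan-GABAergic genes (median -0.06), although the latter call ended without Ctrl replicate 3. None of these list calls at P14 held with an estimated correlation, where the smallest adjusted p was 0.437.

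No gene passed limma at P14 (0 of 15873), and 479 had an unadjusted p below 0.05 (256 higher and 223 lower, 794 expected by chance). edgeR called 0 of 15891, with 462 at unadjusted p below 0.05. DESeq2 called 3 higher (Nr4a3, Fosl2 and Baiap2l1) and 2 lower (Gm10020 and D430036J16Rik). The last 3 of these names were chosen after their values were seen. The groups did not overlap in 337 genes, or 2.12%, against 2.86% by chance. Leaving out 1 library gave limma counts of up to 5. Without Ctrl replicate 4 the 5 were Rpl15-ps2, Lrat, Gm10020, Gm8822 and D430036J16Rik. Without PNS replicate 2 the 1 was Gm6356, without PNS replicate 3 it was Baiap2l1, and without PNS replicate 4 the 3 were A330040F15Rik, Ppfibp1 and Dhx57. All but Ppfibp1 were named after their values were seen.

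Nr4a3 (ENSMUSG00000028341, chromosome 4, 48045153 to 48086447) was higher by 55.8% in PNS at P14, with all 4 PNS libraries above all 4 controls, a log2 difference of 0.64 ± 0.0832 (SE), a limma adjusted p of 0.209 and a DESeq2 adjusted p of 2.4e-07. Fosl2, an AP-1 subunit (ENSMUSG00000029135, chromosome 5, 32135801 to 32157842), averaged 952 ± 126 and 1413 ± 200, with a limma adjusted p of 0.988 and a DESeq2 adjusted p of 0.0411. Pdk1, which inhibits pyruvate dehydrogenase, averaged 1127 ± 67.2 and 1387 ± 70.7, and Spry4, an inhibitor of growth factor signalling, 464 ± 59.4 and 633 ± 66.8. AC161763.1, known only by a clone-based name, averaged 3841 ± 260 and 5544 ± 1044. Among the genes with the smallest p in the other direction Ppfibp1, a liprin, averaged 1155 ± 33.2 and 881 ± 124, and Itih5 1162 ± 73.5 and 838 ± 142. Tbc1d30 averaged 3273 ± 327 and 2469 ± 345, and Zfp9 928 ± 42.8 and 778 ± 34.3. The limma adjusted p of these genes besides Nr4a3 was 0.988. For Ppfibp1 it was 0.0425 without PNS replicate 4.

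Of the 34 lists 13 were called by camera at P14, 0 with an estimated correlation (smallest adjusted p 0.437), 0 by fry and 0 by the exact permutation test. In the permutation test no list could pass on its own after adjustment. Immediate early genes were positive in 21 of 27 (median 0.36, adjusted p = 3.08e-10, and adjusted p = 0.437 with an estimated correlation), with Nr4a3 and Fosl2 among them. In the list 0 genes were called over all genes and 2 (these) adjusted over the list alone. Fosb averaged 357 ± 184 and 745 ± 282 and Egr4 4018 ± 797 and 5736 ± 1188. Their list scores were -0.22, -0.35, 0.22 and -0.37 in Ctrl and 0.42, 0.40, -0.20 and 0.11 in PNS, so 2 PNS libraries lay above every control. Without Ctrl replicate 2 the immediate early median was 0.23. Depth differed between the groups (48.8 M reads in Ctrl and 31.8 M in PNS on average), and with log2 recovered reads as a covariate the immediate early median was 0.16 (adjusted p = 6.8e-06). Ribosomal protein genes were positive in 78 of 80 (adjusted p = 8.99e-21, and adjusted p = 0.454 with an estimated correlation), with Rpl34 at 0.25, Rps21 at 0.23, Rpl41 at 0.20 and Rplp1 at 0.30. PNS replicate 4 had the highest ribosomal score (0.24 against -0.13 to -0.03 in Ctrl), and without it the median was 0.06. Oxidative phosphorylation genes were positive in 72 of 75 (adjusted p = 9.98e-16, and adjusted p = 0.437 with an estimated correlation), with Ndufa2 at 0.28, Atp5k at 0.27, Atp5l at 0.20 and Cox5a at 0.14. Proliferation genes were negative in 30 of 36 (median -0.15, adjusted p = 3.28e-05, and adjusted p = 0.454 with an estimated correlation), with Nusap1 at -0.53, Aurkb at -0.67, Mcm3 at -0.28 and Cenpa at -0.37.

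**Figure D3:**
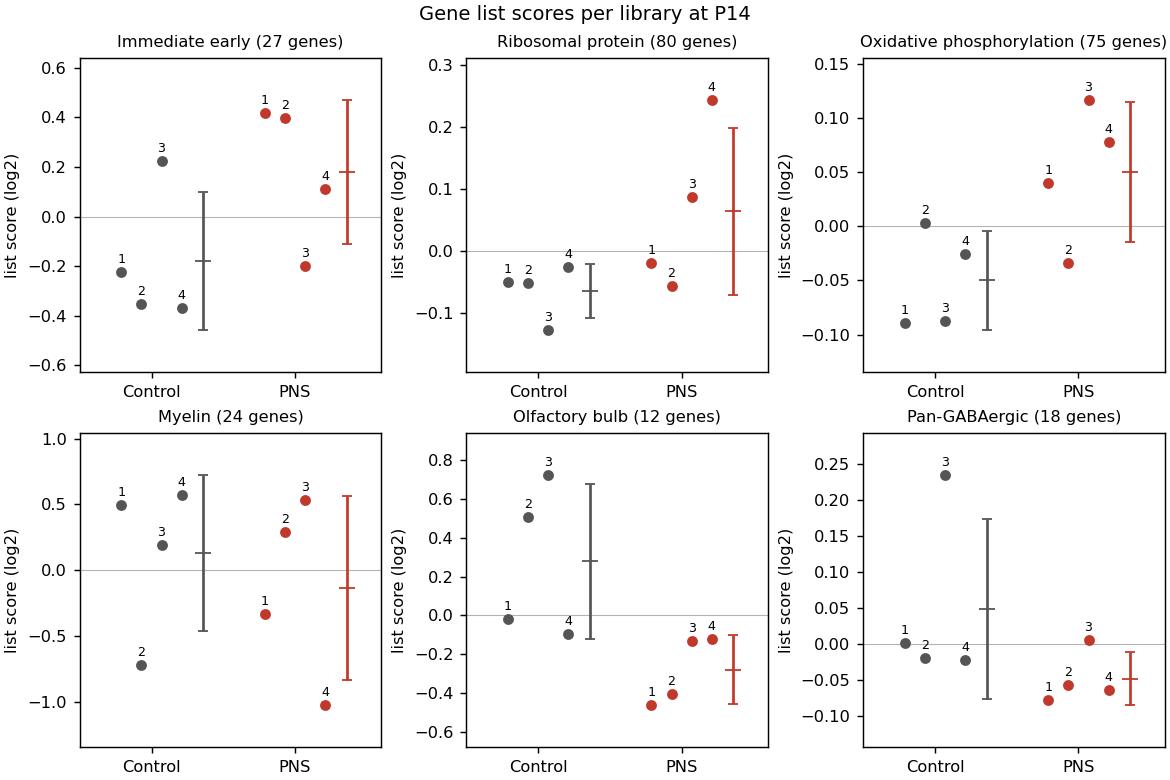
Scores of gene lists at P14, as the mean over a list's genes of log2(value + 1) minus each gene's mean over the 8 libraries (vertical axis, log2 units), for Ctrl and PNS; points are libraries labelled by replicate number and bars are mean ± SD (n = 4). In the immediate early list PNS replicates 1 and 2 (0.42 and 0.40) lie above every control, and in the pan-GABAergic list Ctrl replicate 3 (0.23) lies apart from the other libraries.

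Pan-GABAergic genes were negative in 12 of 18 members (median -0.06, adjusted p = 0.0429, and adjusted p = 0.776 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. Gad1 averaged 6373 ± 562 and 5761 ± 440, Gad2 6564 ± 159 and 6172 ± 240, Dlx1, a transcription factor of the interneuron lineage, 1968 ± 477 and 1696 ± 113, and the predicted gene Gm14204 stood at -0.64. Ctrl replicate 3 had a list score of 0.23, against -0.02 to 0.00 in the other controls and -0.08 to 0.01 in PNS, and it also had the highest olfactory bulb score (0.73). The pan-GABAergic adjusted p was 0.519 without Ctrl replicate 3 (median -0.02), 0.279 without PNS replicate 1, 0.208 without PNS replicate 2 and 0.0533 without PNS replicate 4, and the median was -0.10 without PNS replicate 3. With log2 recovered reads as a covariate the median was -0.06 (camera adjusted p = 0.00555 at the preset correlation, not repeated with an estimated one). Genes of medial and caudal ganglionic eminence interneurons had adjusted p-values of 0.613 and 0.465, and GABA receptor genes one of 0.733. In the medial eminence list the median (0.02) was positive while the mean (-0.04) and the test were negative. Sst averaged 9142 ± 502 and 9275 ± 1431, Pvalb 222 ± 68.8 and 209.7 ± 81.8, and Vip 1194 ± 243 and 1082 ± 273. Lhx6 averaged 1214 ± 91.5 and 1225 ± 85.3, Slc32a1 3709 ± 246 and 3669 ± 349, and Npy 1996 ± 136 and 1926 ± 268. Cck averaged 17508 ± 1359 and 19080.0 ± 3415, Calb2 1223 ± 165 and 1116 ± 93.1 and Htr3a 121 ± 49.2 and 149.6 ± 49.2. Reln averaged 5660.0 ± 643 in Ctrl and 7245 ± 1268 in PNS (log2 difference 0.35 ± 0.118 SE, limma adjusted p 0.988), with all PNS libraries above all controls. Nr3c1 (2515 ± 192 and 2565 ± 274), Nr3c2 (931 ± 70.2 and 869.5 ± 56.8), Fkbp5 (1014 ± 94.6 and 940.0 ± 37.2), Slc12a2 (1091 ± 110 and 1026 ± 91.7), Slc12a5 (25997 ± 1040 and 26786 ± 3596) and Mbp (21650.3 ± 8460 and 17771 ± 8678) had limma adjusted p-values from 0.988 to 0.991. Leaving out 1 library flipped the sign for Sst (-0.09 without PNS replicate 3), Pvalb (0.11 without PNS replicate 4), Cck (-0.01 without PNS replicate 4), Slc12a5 (-0.05 without PNS replicate 4), Lhx6, Slc32a1, Npy and Nr3c1, the last 4 with values of -0.02 to 0.02.

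Olfactory bulb genes were negative in 9 of 12 at P14 (median -0.43, adjusted p = 0.00367, and adjusted p = 0.437 with an estimated correlation), with Eomes at -2.31, Tbx21 at -2.10, Cdhr1 at -0.50 and Sp8 at -0.58. Eomes and Tbx21 were weakly expressed, and their drops came mostly from Ctrl replicates 2 and 3. Eomes was counted at 7.43, 87.2, 100.5 and 3.20 in Ctrl and at 2.60 to 4.96 in PNS. Tbx21 was counted at 5.45, 22.7, 46.7 and 8.80 in Ctrl and at 0 to 6.08 in PNS. The list score was 0.51 and 0.73 in Ctrl replicates 2 and 3, -0.02 and -0.09 in the other controls and -0.46 to -0.12 in PNS, and without Ctrl replicate 3 the adjusted p was 0.0643 (median -0.19). Meningeal genes were negative in 21 of 22 (median -0.14, adjusted p = 0.00252, and adjusted p = 0.79 with an estimated correlation), with Cyp1b1 at -0.39, Col3a1 at -0.28, Islr at -0.29 and Mgp at -0.25. Without PNS replicate 3 the meningeal median was 0.02 (adjusted p = 0.875), and it was -0.31 without PNS replicate 4, -0.09 without Ctrl replicate 3 and -0.09 without Ctrl replicate 4. Myelin genes were negative in 22 of 24 (median -0.26, adjusted p = 0.00772, and adjusted p = 0.79 with an estimated correlation), with Myrf at -0.25, Gjc3 at -0.25 and Enpp2 at -0.12. PNS replicate 4 had the lowest myelin score (-1.03), and without it the median was 0.01 (adjusted p = 0.954). The myelin adjusted p was 0.181 without Ctrl replicate 1 (median -0.15), 0.37 without Ctrl replicate 4 (-0.10) and 0.168 without PNS replicate 1 (-0.20), and the median was -0.59 without Ctrl replicate 2, -0.40 without PNS replicate 2 and -0.46 without PNS replicate 3. Endothelial genes were positive in 19 of 22 (median 0.08, adjusted p = 0.00772, and adjusted p = 0.79 with an estimated correlation), with Slco1c1 at 0.19, Esam at 0.17, Ramp2 at 0.17 and Eng at 0.21. The endothelial median was 0.03 (adjusted p = 0.954) without PNS replicate 4 and 0.18 without PNS replicate 3, and the adjusted p was 0.0834 without Ctrl replicate 2 and 0.059 without PNS replicate 2.

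Deep-layer genes were positive in 14 of 18 at P14 (median 0.13, adjusted p = 0.00373, and adjusted p = 0.437 with an estimated correlation), with Fezf2, the fate determinant of subcortical projection neurons, at 0.14, Tle4 at 0.18, Crym at 0.33 and Hs3st4 at 0.19. Without PNS replicate 2 the deep-layer adjusted p was 0.236. Protein folding genes were positive in 20 of 26 (median 0.06, adjusted p = 0.0113, and adjusted p = 0.437 with an estimated correlation), with Hspa5 at 0.12, Calr at 0.15, Pdia4 at 0.15 and Xbp1 at 0.12, and the call ended without Ctrl replicate 4 (adjusted p = 0.0948). Hypoxia and glycolysis genes were positive in 17 of 24 (median 0.06, adjusted p = 0.0272, and adjusted p = 0.437 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone (Pdk1). P4ha1 stood at 0.18, Pgam1 at 0.10 and Vegfa, itself a hypoxia target, at -0.29. The hypoxia call ended without Ctrl replicate 2, 3 or 4 (adjusted p = 0.0834, 0.054 and 0.0725) or PNS replicate 1, 2 or 4 (0.0726, 0.0529 and 0.0533), and the median was 0.10 without Ctrl replicate 1 and 0.03 without PNS replicate 4. Glutamatergic synapse genes were positive in 28 of 38 (median 0.06, adjusted p = 0.0358, and adjusted p = 0.789 with an estimated correlation), with Grin2b at 0.23, Grik3 at 0.09 and Grik2 at -0.19. The glutamatergic median was 0.00287 (adjusted p = 0.954) without PNS replicate 4, 0.10 without PNS replicate 1 and 0.10 without PNS replicate 3, and the call ended without Ctrl replicate 1, 3 or 4 (adjusted p = 0.0551, 0.054 and 0.126) or PNS replicate 2 (0.0521). It ended as well with log2 recovered reads as a covariate (median 0.04, adjusted p = 0.0516).

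The remaining lists did not pass at P14. Their adjusted p-values were 0.0517 for mitochondrially encoded genes, 0.109 for monoamine receptors, 0.166 for oligodendrocyte precursors, 0.174 for cholesterol synthesis, 0.515 for astrocytes and 0.529 for perineuronal nets. They were 0.562 for pericytes, interferon-stimulated and striatal genes, 0.611 for the stress axis, 0.635 for upper layers, and 0.648 for immature neurons. They were 0.703 for microglia, 0.79 for glucocorticoid-responsive, erythroid and choroid plexus genes, 0.864 for neural progenitors and 0.877 for thalamic genes. Neural progenitor genes had a median of 0.01 and a mean of -0.09, and thalamic genes a median of -0.00259 and a mean of 0.02, with negative tests in both lists. With log2 recovered reads as a covariate mitochondrially encoded (median 0.11, adjusted p = 0.0308) and cholesterol synthesis genes (0.08, 0.0174) were higher in PNS.

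The third comparison asked whether the difference between PNS and Ctrl itself differed between the ages. The list with the smallest p was that of ribosomal protein genes, which went from a median of -0.06 at P1 to 0.12 at P14, and deep-layer genes went from -0.16 to 0.13. Meningeal genes went the other way, from 0.56 to -0.14, as did olfactory bulb genes, from 0.55 to -0.43. None of these list differences held with an estimated correlation. Among single genes Id3, an inhibitor of basic helix-loop-helix factors, differed by 0.36 at P1 and by -0.22 at P14, and Kcnn1, a calcium-activated potassium channel, by -0.39 and 0.14.

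In limma 0 of 16418 genes passed for this difference, with 973 at unadjusted p below 0.05 (363 positive and 610 negative, 821 expected by chance). edgeR called 0 of 17139, with 1037 at unadjusted p below 0.05, and DESeq2 called 2 positive and 7 negative. Without PNS replicate 4 of P1 the limma count was 74, and it was 1 without Ctrl replicate 4 of P14 and 1 without PNS replicate 2 of P14. Sema3c (0.46), Pantr1 (0.42), Kcnn1 (0.53), Rpl34 (0.34) and Sostdc1, a secreted antagonist of BMP and Wnt signalling (1.29), had the smallest p-values with a positive difference. Id3 (-0.58), Plat (-0.49), Itih5 (-0.86), Cygb (-0.58) and the predicted gene A830036E02Rik (-3.65) had the smallest with a negative one. Their limma adjusted p-values ranged from 0.491 to 0.716. In DESeq2 all but Sema3c, Pantr1 and Sostdc1 passed, with adjusted p from 0.0022 (A830036E02Rik) to 0.048 (Rpl34). Without PNS replicate 4 of P1 the limma adjusted p was 0.0428 for Id3, 0.0279 for Plat, 0.0219 for Itih5 and 0.0315 for Cygb. camera called 16 lists for the difference and 0 with an estimated correlation, where the smallest adjusted p was 0.095 for deep-layer genes. The interneuron lists did not pass for the difference between ages, with adjusted p-values of 0.165 for pan-GABAergic, 0.59 for medial eminence and 0.0746 for caudal eminence genes.

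No gene was called by limma at both ages, since 0 were called at either. At an unadjusted p below 0.01 there were 174 genes higher at P1 and 28 higher at P14, with 0 shared (0.314 expected). There were 42 and 26 lower, with 0 shared (0.0704 expected), among 15502 genes tested at both ages (two-sided Fisher's exact test, p = 1 in each direction). Across genes, which are not independent replicates, the log2 differences at the 2 ages had a Pearson r of -0.0754 and a Spearman rho of -0.0717.

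The last comparison gave the developmental background in control cortex, from P1 to P14. Myelin, astrocyte and synaptic genes rose, and proliferation, immature neuron and ribosomal protein genes fell. Among interneuron genes Vip, a neuropeptide of caudal eminence interneurons, was 17.3-fold higher at P14 (2.09 ± 0.863 CPM at P1, 35.97 ± 7.50 at P14). At P14 Cck was 8.63-fold, Gad2 6.05-fold, Sst 2.99-fold, Gad1 2.37-fold and Slc32a1 2.30-fold higher, while Lhx6 was 2.97-fold and Reln 2.17-fold higher at P1. Mbp rose 13.1-fold, Slc12a5, the chloride extruder of mature neurons, 5.76-fold, Nr3c1 4.02-fold and Nr3c2 1.63-fold, and Fkbp5 was 2.13-fold higher at P1.

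edgeR on the recovered reads called 5970 genes higher and 6237 lower at P14 of 17139 tested, where 12550 had an unadjusted p below 0.05. The adjusted p of the genes named above ran from 1.24e-13 (Cck) to 0.000941 (Nr3c2). Npy was 1.46-fold higher (adjusted p = 0.0182, and 0.0653 without Ctrl replicate 3 of P1), and Calb2 (adjusted p = 0.143), Htr3a (0.516) and Slc12a2 (0.973) did not pass. Pvalb was not tested in this comparison. Age coincides with the table and possibly the sequencing run, so for a single gene the 2 cannot be told apart here. Against a run or table difference as the whole cause stand lists that moved far in opposite directions. Myelin genes were called higher at P14 in 20 of 21 (median 3.08) and proliferation genes lower in 36 of 36 (median -2.55).

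Myelin genes rose in 20 of 21 (median log2 change 3.08), for example Mag. Astrocyte genes rose in 17 of 20 (1.63), for example Slc1a2, the main glutamate transporter, which was 14.1-fold higher. Glutamatergic synapse genes rose in 30 of 38 (1.198), for example Slc17a7, 26.0-fold. GABA receptor and chloride transporter genes rose in 18 of 19 (0.87). Stress axis genes rose in 10 of 12 (1.73), for example Crhbp, 16.9-fold. Immediate early genes rose in 20 of 27 (1.38), for example Arc, 31.6-fold, while Nr4a3 and Fosl2 were 2.16-fold and 3.73-fold higher at P1. Proliferation genes fell in 36 of 36 (-2.55), for example Top2a, 12.3-fold higher at P1. Immature neuron genes fell in 18 of 20 (-1.91), for example Dcx, 12.5-fold, and ribosomal protein genes in 79 of 80 (-1.18), for example Rplp0, 3.50-fold. Pan-GABAergic genes split, with 5 higher, among them Gad1, Gad2, Slc32a1 and Elfn1, and 11 lower, among them Dlx1 (3.02-fold higher at P1) and Dlx2 (3.97-fold). Medial eminence genes rose in 10 and fell in 6 of 21, and caudal eminence genes rose in 9 and fell in 9 of 21. Meningeal genes fell in 17 of 22 and deep-layer genes in 9 of 18. The examples in these lists other than the interneuron genes and hormone receptors were chosen after their values were seen.

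**Figure D4:**
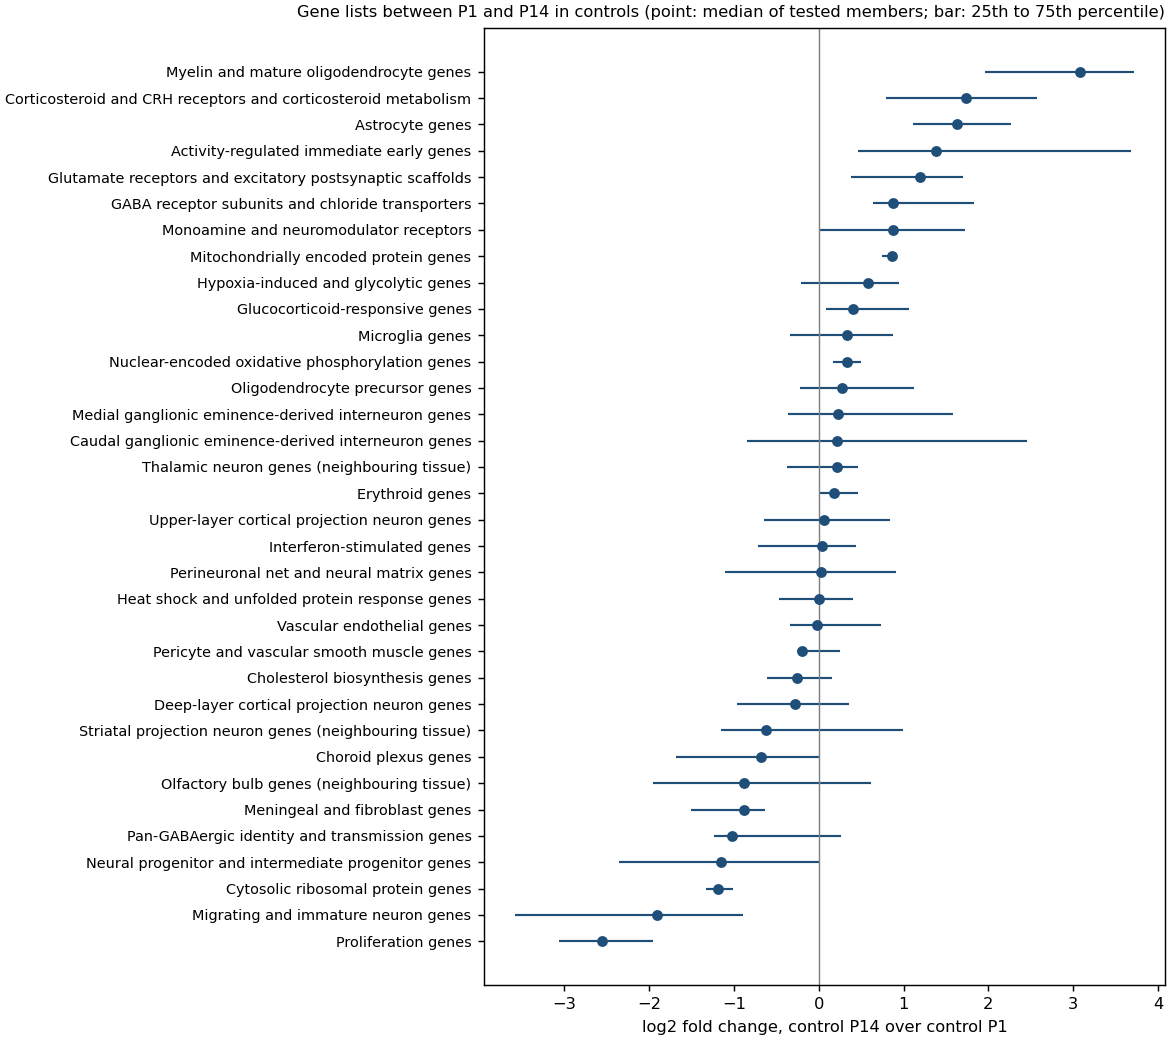
Log2 change from P1 to P14 in control cortex for each gene list (horizontal axis, log2 units); points are list medians and bars run from the lower to the upper quartile over the list's genes. Myelin genes have the highest median (3.08) and proliferation genes the lowest (-2.55).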

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

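The test that asked in how many olfactory bulb genes PNS replicate 4 exceeds the controls, and the test that asked how many PNS libraries exceed every control for immediate early genes, were chosen after the result was seen, as were the splits of the libraries for gene counts at P1 and at P14. Of 178 groups of 4 libraries tested for 1 value far from the other three, 14 had one, and chance gives about 1 in 20, or 9.

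At P1 these single values lay far from the rest of their group. Mbp was 2095.7 in Ctrl replicate 1 (2647 to 2717 in the others). Exosc9 was 938 in PNS replicate 3 (1143 to 1173), and Nr3c2 was 1296 there (890.5 to 954). Among list scores, endothelial genes stood at -0.27 in Ctrl replicate 3 (-0.05 to -0.02), interferon-stimulated genes at 0.0502 in Ctrl replicate 1 (-0.18 to -0.16) and folding genes at 0.10 in Ctrl replicate 2 (-0.03 to -0.01). In PNS replicate 3 pericyte genes stood at 0.45 (0.03 to 0.09) and upper-layer genes at -0.12 (-0.07 to -0.06), and in PNS replicate 4 myelin genes stood at -0.30 (0.34 to 0.35).

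At P14 the pan-GABAergic score was 0.23 in Ctrl replicate 3 (-0.02 to 0.00 in the others) and the deep-layer score 0.28 in PNS replicate 2 (-0.03 to 0.01). Sst was 11405 in PNS replicate 3 (8339.5 to 8761), Reln 9129.7 in PNS replicate 4 (6479 to 6859) and Cck 24189.5 in PNS replicate 4 (17049 to 17654).

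The PNS effect differed between the ages in 16 lists by camera with a preset correlation, and in 0 with an estimated correlation, while the other lists did not pass. The adjusted p was 2.51e-21 for ribosomal protein, 5.52e-17 for meningeal, 2.52e-06 for olfactory bulb, 2.97e-06 for deep-layer, 0.0001004 for oxidative phosphorylation, 0.000335 for myelin, 0.001404 for folding, 0.00235 for immediate early, 0.00351 for astrocyte and 0.00659 for pericyte genes. It was 0.0126 for proliferation, 0.0148 for striatal, 0.0222 for endothelial, 0.0328 for upper-layer, 0.0328 for thalamic and 0.03496 for glucocorticoid-responsive genes. Olfactory bulb genes went from a median of 0.55 at P1 to -0.43 at P14, meningeal genes from 0.56 to -0.14 and deep-layer genes from -0.16 to 0.13.

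Olfactory bulb genes were higher in PNS replicates 1, 2 and 3 at P1. A stress effect of this kind present in all 4 PNS libraries is argued against by PNS replicate 4, whose score (-1.19) lay below every control (-1.13 to 0.14) and which exceeded the highest control in 2 of 15 genes. A candidate explanation is olfactory bulb tissue in part of the dissected pieces. A set of 17 further olfactory genes had a median of 0.42, at percentile 100 of 10000 random lists matched for expression. The random lists held unrelated genes, while genes of 1 tissue can vary together. The percentile thus shows that the further genes rose as a set, and does not measure chance among libraries. Gap43 (-0.13) and Sall3 (-0.0056), named after their values were seen, were negative, while the other members were positive. Gad1 among the 17 is also a pan-GABAergic gene, so the set is not of the bulb alone. Of the 15 genes 9 reached a value of 10 in every control and 4 are in another list, and among the 17 further genes these counts are 15 and 3. A stress effect on the size or position of the bulb, or on the tissue itself, stays open and was not tested.

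Deep-layer genes were lower in all 4 PNS libraries at P1. Deep-layer genes lay below 20 general neuronal genes (median -0.08) by a difference of -0.0835 (95% interval over genes -0.27 to -0.0115). That interval comes from resampling genes, which are not independent replicates, and does not measure the spread between libraries. The 20 genes also included Neurod2, an immature neuron gene, and Slc17a7, a glutamatergic synapse gene, so they do not track neurons in general alone. A lower share of neurons in general is therefore not excluded, and the general neuronal genes had a negative median themselves. Against dilution by olfactory bulb tissue as the whole cause stand the median with the olfactory bulb score as a covariate (-0.21, against -0.16 without it, camera adjusted p = 0.000788) and PNS replicate 4, which had the lowest olfactory score (-1.19) and a deep-layer score of -0.13, below every control (0.09 to 0.20). Dilution is not excluded, because the interval of that median, also from resampling genes, reached -0.00474. Besides, only PNS replicate 4 does not lie above every control in the olfactory score. A lower share of deep-layer neurons, or lower expression within them, may remain and was not tested.

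Ribosomal protein and oxidative phosphorylation genes, and separately immediate early genes, were higher in PNS at P14. Fewer nuclear-retained transcripts across the PNS libraries are argued against as a cause by the scores below, and stay open for PNS replicate 4 alone. The score of 12 nuclear RNAs was 0.62, 0.69, 0.00047 and -1.37 in PNS and -0.20, 0.14, 0.36 and -0.23 in Ctrl. PNS replicates 1 and 2 thus lay above every control and PNS replicate 3 among the controls, where this cause needs lower scores. PNS replicate 4 had the lowest nuclear score and the highest ribosomal score (0.24). With the nuclear score as a covariate the mean of the ribosomal and oxidative phosphorylation medians was 0.0986, and 0.102 before. That fit adds little to the scores themselves, because the nuclear score hardly differed between the groups on average. PNS replicate 4 alone cannot be told apart from the group, since without it the mean was 0.0642, still positive but lower, and 4 libraries are too few to place it. For immediate early genes an effect in all 4 PNS libraries stays open, as 2 of 4 lay above every control and the other two lay among the controls (-0.37 to 0.22), while depth cannot be told apart from stress, since the median was 0.16 with log2 reads as a covariate and 0.36 without, and depth differed between the groups. Handling before dissection, which could also act on immediate early genes, was not tested.

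Other splits of the 8 libraries show what grouping alone gives. Where the real split called 0 genes in limma every split gives as many, so the splits say nothing about chance: 35 of 35 at P1 (highest other 24, with 1115 genes at unadjusted p below 0.05), 35 of 35 at P14 (highest other 5, 479 genes) and 100 of 100 for the difference between ages (highest other 14, 973 genes). DESeq2 called 70, 5 and 9 genes in the real split, and edgeR 0 in each. For lists at P1 chance cannot be excluded, with 16 in the real split and 21 in the highest other, and 7 of 35 giving as many. For genes and for lists at P1 the highest split set Ctrl replicate 1 and PNS replicates 1, 2 and 3 against the rest. That split follows the olfactory bulb scores rather than the PNS and Ctrl labels, and whether stress had a part in these scores was not tested. For lists at P14 only the real split gave 13 (1 of 35, the smallest share that 35 splits allow), by a margin of 1 list (highest other 12). Chance is not excluded, since these are calls at the preset correlation, and 0 lists held with an estimated correlation or fry. Exact permutation also called 0, but its smallest possible p of 0.0286 let no list pass on its own after adjustment. For age in controls chance is excluded (real 12225 in a fit of the controls alone, highest other 1, 1 of 35).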

How the results depend on the processing

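The count models on recovered reads, the omission of PNS replicates 2 and 3 or 1, 2 and 3 at P1, TMM for lists, the exact permutation of list scores, log2 recovered reads as a covariate for lists and the olfactory bulb score as a covariate for lists at P1 were chosen after seeing the data. The other alternatives were TMM or median-ratio rescaling, no filter, a stricter filter, pseudocounts of 0.5 and 10, the replicate block, 1 fit of all libraries, leaving out each library, an estimated correlation, fry, RLE scaling for age and an overlap at p 0.01.

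At P1 limma called 0 genes, against 1 with all 16 libraries in 1 fit, 70 with DESeq2 and 0 to 123 without 1 library. At P14 it called 0, against 5 with DESeq2 and 0 to 5 without 1 library, and for the difference between ages 0, against 9 with DESeq2 and 0 to 74 without 1 library. The other alternatives with more than 1 library in each group gave 0 for each, 1115, 479 and 973 genes having an unadjusted p below 0.05 in limma. The cause of the higher DESeq2 counts was not tested.

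Lists called were 16 at P1 and 13 at P14, and with an estimated correlation 0 and 0, with fry 0 and 0, and with exact permutation 0 and 0. The permutation counts say little, because no list could pass that test on its own after adjustment. Leaving out 1 library gave 12 to 18 and 9 to 14 lists. With the replicate block 18 and 13 lists and 0 genes were called, but of the 8 PNS libraries only P1 replicates 3 and 4 correlated best with the control of their own number (0.133 and 0.211), so numbers were not read as pairs.

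Over the alternatives list results kept direction and call in 295 cases, lost the call in 116 and reversed in 13, some of the latter in the fit with 1 PNS library. With log2 recovered reads as a covariate 19 lists were called at P1 and 14 at P14. With the olfactory bulb score as a covariate 17 lists were called at P1, and the astrocyte (median -0.021) and interferon (-0.0468) lists reversed. Without PNS replicates 2 and 3 the interferon median at P1 was 0.0193, on the other side by camera. Without PNS replicates 1, 2 and 3, which leaves 1 PNS library, the interferon median was -0.23. In that fit medians were -0.21 for astrocyte, 0.0108 for immature neuron, -0.15 for myelin and -0.0825 for olfactory bulb genes. They were -0.0026 for ribosomal protein (direction up by camera) and -0.10 for thalamic genes. At P14 medians without 1 library ran from -0.31 to 0.022 for meningeal, from -0.59 to 0.0117 for myelin and from 0.00287 to 0.104 for glutamatergic synapse genes. The causes were not tested, except that PNS replicates 1, 2 and 3 carry the olfactory bulb signal.

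The comparison P14 vs P1 in controls gave 12207 genes, 12168 with RLE scaling, 12304 with no filter and 11669 to 11905 without 1 library. The overlap between ages was 0 at each threshold. Depth ranged 1.73-fold at P1 and 4.84-fold at P14, where Ctrl replicate 3 had 15.1 M reads, which limits weakly expressed genes.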

Other observations

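The genes below were all named after their values were seen. The first 4 were picked at P1 because they were high in PNS replicates 1, 2 and 3, and no list of such genes was tested. Foxd3, a neural crest factor, was counted at 205, 454.5 and 339 in PNS replicates 1, 2 and 3, at 0 in PNS replicate 4 and at 0 to 15.5 in Ctrl. Frzb, a secreted Wnt antagonist, was counted at 744, 1943, 1429 and 109 in PNS and at 113 to 297 in Ctrl. Th, the enzyme that commits tyrosine to dopamine synthesis, was counted at 242, 626, 468 and 9.51 in PNS and at 5.64 to 90.7 in Ctrl, and Prss56 at 423, 1322, 1123 and 0.79 against 0 to 142.

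Some genes were on in part of the libraries and nearly off in the rest, whatever the group. A gap of at least 8-fold with at least 2 libraries on each side was found in 14 of 16711 genes at P1 and in 21 of 15873 at P14, and 0 of them separated PNS from Ctrl in full. The genes named next were at P14 high in libraries of only 1 group, unlike most of the 21. Gm10020 stood at 215, 197, 185 and 2.40 in Ctrl and at 1.24 to 5.21 in PNS at P14. At P1 Gm10020 did not follow the groups, at 303, 11.1, 608 and 5.64 in Ctrl and 426, 11.1, 9.73 and 11.9 in PNS. Lrat, which esterifies retinol, stood at 86.7, 81.6, 88.8 and 3.20 in Ctrl and at 0 to 3.96 in PNS at P14. Baiap2l1, an actin regulator, stood at 445, 577, 7.81 and 288.5 in PNS and at 7.93 to 21.02 in Ctrl.

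PNS replicate 4 at P14 stood apart in blood and noncoding RNA. Hbb-bs was counted at 15176 there and at 2465 to 6683 in the other P14 libraries, and Meg3 at 1062 there and at 3049 to 9340 in the others. At P1 Xist was counted at 62.95 in PNS replicate 2 and at up to 5.39 in the other libraries.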
